A study of Mus musculus with 2 samples.

How the data were processed

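Small RNA from the adrenal gland of adult female 5xFAD/CAST mice was sequenced as 2 libraries of 1 group, named biological replicates 1 and 2 in the labels. Per the labels, total RNA was used, the size range of the molecules was below 30, with no unit stated, and the assembly was mm10. The replicates have separate biosamples and a shared donor identifier, which leaves open whether they came from separate animals, so measures of spread describe these samples and may be technical.

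The authors deposited 1 table of raw counts per library, with 1 entry for each of 2202 miRNA genes and 3 count columns that carry no names. Per the notes deposited with the tables, the assembly was mm10 and the gene annotation GENCODE M21. The aligner, the counting program, the trimming of adapters and the meaning of the columns are not given in the sources used here. What the columns hold was read from the values. The first is taken as reads of both strands and called the both-strand column, the next as reads of 1 strand and called the strand column, and the last as reads of the other strand. In both libraries the strand columns together equal the both-strand column plus the ambiguous reads counted in each of them, so reads over overlapping genes on opposite strands are missing from the both-strand column and present in the strand columns. Entries that name no gene were kept out of all totals. They held unmapped reads (16.1% of all reads in replicate 1 and 16.5% in replicate 2), multimapping reads (31.6% and 33.6%), reads on no miRNA gene (5.55% and 4.99%) and ambiguous reads (6.12% and 5.24%). Reads with several genomic matches were thus not assigned to genes, which lowers the counts of miRNAs with copies at several loci. A 20-base stretch is shared with another gene by 1084 of the 2202 genes, and 64 genes overlap an opposite-strand miRNA gene. PCR reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only, and ligation bias affects comparisons between genes.

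Before the data were examined, the groups, tests, filters, alternatives, gene lists and the rule for named genes were fixed. The rule for the count column was to use the one named as sense-strand reads and otherwise the unstranded one. As none is named, the both-strand column is the main one, and values from the strand column are given for genes it changes. All 2202 gene identifiers matched the GENCODE M21 annotation, which gave symbols, mm10 coordinates and overlapping genes, and older symbols in the lists were matched through RefSeq synonyms.

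Counts were divided by the miRNA-gene total of the library to give CPM. The depth on miRNA genes was 3159960 and 6119201 reads, a ratio of 1.94, and a count of 0, taken as an upper limit of 3 counts, allows 0.949 and 0.490 CPM. Shares have exact Clopper-Pearson intervals at 95%. A gene was called detected with at least 10 reads in each library. Differences between the libraries were tested per gene with Fisher's exact test (two-sided, replicate 2 against replicate 1) for genes with at least 10 reads in both together, with Benjamini-Hochberg adjustment at 0.05. Under TMM and DESeq2 size factors an exact binomial test with scaled totals took its place. edgeR's exact test used the same plain totals as Fisher's test and the common dispersion described next. Log2 ratios used an offset of 0.5 counts. The biological coefficient of variation is the square root of edgeR's common dispersion in a model with an intercept only, with TMM normalization. Correlations across genes used log2(CPM + 1). Neighboring genes were consecutive genes on the same strand within 10 kb, tested with 100000 permutations of values over genes. The median log2 ratio of a list with at least 3 detected members was placed among 10000 random lists of the same size, matched on abundance. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

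The genes named are the 25 with the highest mean CPM, the 5 with the largest log2 ratio in each direction among genes with a mean of at least 100 CPM and an adjusted p under 0.05, and up to 3 of the most abundant detected members of each list. A selection of these is described, and genes outside the rule are marked as such. The lists come from general knowledge of miRNA families, genomic clusters and tissue markers. They cover red cell, immune, endothelial, smooth muscle, striated muscle, liver, kidney and intestine, epithelial, pancreas, brown fat, neuroendocrine, neuronal, gonad and embryonic stem cell markers, ACTH and steroid synthesis, hypoxia, the miR-183, miR-17-92, Dlk1-Dio3, Sfmbt2 and X-linked clusters, and the let-7, miR-30, miR-29, miR-26, miR-10 and miR-196, miR-99 and miR-100, miR-148 and miR-152, miR-181, and miR-15 and miR-16 families.

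The procedures were tested on simulated data. With counts drawn from the real means for the comparison of the 2 libraries, Fisher's exact test called 71.5% of 200 genes changed 2-fold, among 428 genes tested, and 100% of those with at least 200 reads. It called 0 genes when none was changed. The exact binomial test with totals of unchanged genes, which are known only in a simulation, called 1.24% of unchanged genes. These counts were drawn with counting error only and lack the spread seen between the real libraries. They therefore do not give the rate of false calls in the real data. A simulated coefficient of variation of 30% was recovered as 29.2% over 329 genes. For 328 genes, the permutation test on neighbors gave p = 0.361 for unrelated values and p = 1e-04, the smallest its draws can give, for planted shared values. Most of the planted variation was shared between neighbors, so the power to find weaker sharing was not checked.

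The alternatives were the strand column, minimums of 1 and 100 reads, TMM and DESeq2 scaling, library totals without the most abundant gene, edgeR's exact test with the common dispersion, pseudocounts of 0.5 and 5, a DESeq2 gene-wise dispersion, leaving out each replicate, and neighbor distances of 1 and 50 kb. Signal tracks and alignments named in the notes were not used here. Mature arms were not separated, and reads with several genomic matches were not analysed here.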

Results

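MicroRNA sequencing libraries were made from the adrenal gland of adult female 5xFAD/CAST mice aged 8 to 10 months. 5xFAD is a transgenic mouse model of Alzheimer's disease and CAST is an inbred strain derived from wild castaneus mice, and the labels do not give the transgene status of single animals. The labels describe 2 biological replicates of 1 group, taken from separate biosamples that carry the same donor identifier, so the spread between them may be partly technical. Replicate 1 held 7774567 reads and replicate 2 held 15391360 reads, of which 3159960 and 6119201 were counted on annotated microRNA (miRNA) genes. Levels are given as CPM, the reads of a gene scaled to a library total of 1000000 miRNA-gene reads, with the mean ± SD over the 2 libraries. With a single group, the design gives the repertoire of adrenal miRNAs, their levels and the differences between the libraries, and it gives no contrast between conditions. Counts are per precursor gene, so the arms of a hairpin are not separated.

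The first question was which miRNA genes the adrenal gland expressed and at what level. In the both-strand column, the let-7 family led the profile. That column misses reads over overlapping genes, so it hardly counts 4 genes found among the 25 most abundant of the strand column. Among these are Mir126a at rank 4 and Mir378a at rank 8, described below. Mirlet7b reached 122191 ± 478 CPM (SD, n = 2) and Mirlet7g 112338 ± 19367 CPM, while Mirlet7i and Mirlet7d stood at 48450 ± 3405 and 44774 ± 7471 CPM. Mir10a, which lies in a Hox gene cluster, reached 62618 ± 6658 CPM, and Mir375, a miRNA enriched in endocrine cells, reached 51619 ± 2589 CPM. Mir139 and Mir22 followed at 43211 ± 1052 and 41903 ± 8551 CPM. Mir23b and Mir23a were at 36453 ± 839 and 36209 ± 9989 CPM, values that are uncertain because each gene shares a 20-base stretch with another miRNA gene. Mir143, known from smooth muscle, was at 24746 ± 1979 CPM and Mir26b at 24154 ± 110 CPM. These ranks and the shares that follow cover only reads assigned to a single gene. Multimapping reads, 31.6% of all reads in replicate 1 and 33.6% in replicate 2, were assigned to no gene and could change them. Mirlet7b alone took 12.2% ± 0.05 of the assigned reads, the 10 most abundant genes 60.0% ± 2.10 and the 25 most abundant 83.5% ± 0.29 (SD, n = 2). The share of the leading 10 was 58.5% in replicate 1 (exact Clopper-Pearson 95% interval 58.4 to 58.5%) and 61.5% in replicate 2 (61.4 to 61.5%).

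**Figure D1:**
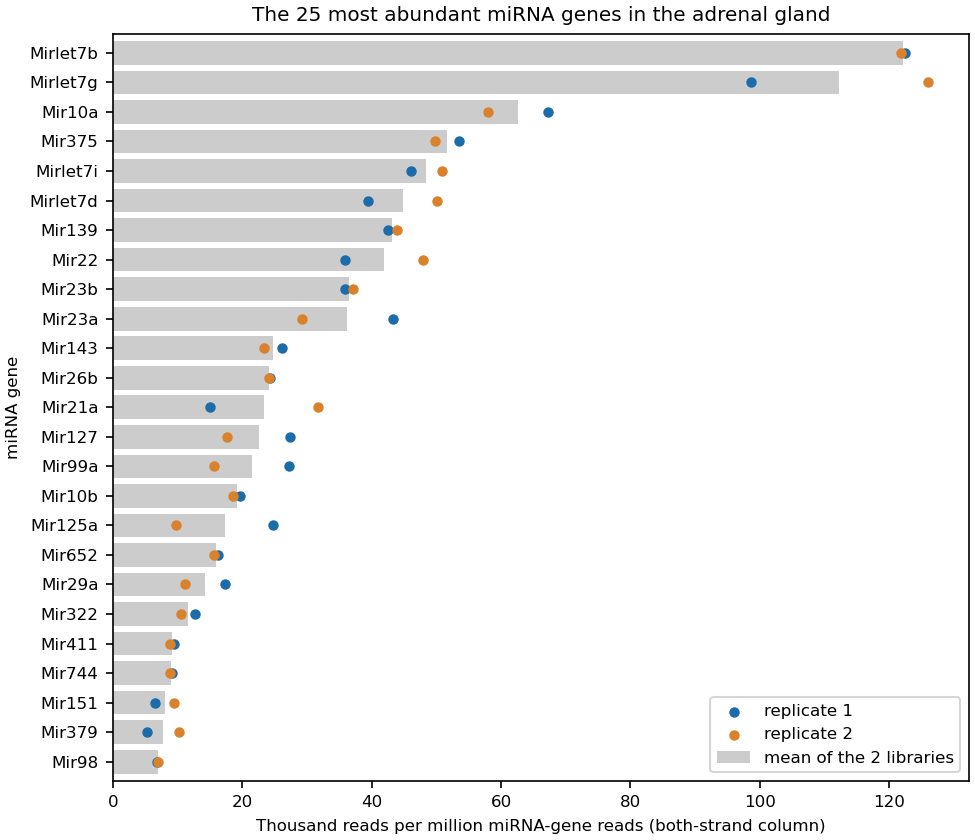
CPM of the 25 most abundant miRNA genes of the both-strand column, in units of 1000 CPM, with a grey bar for the mean of the 2 libraries and a point for each library. Genes counted almost only in the strand column, such as Mir126a and Mir378a, are missing from it. Reads with several genomic matches are not counted either. Mirlet7b and Mirlet7g lead at 122191 and 112338 CPM on average, and Mir21a shows a wide gap, at 14965 CPM in replicate 1 and 31768 CPM in replicate 2.

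In the mouse genome build mm10, Mirlet7b (ENSMUSG00000065564.1) lies on chromosome 15 at 85707319 to 85707403, in an exon of the noncoding gene Lncppara. Mirlet7g (ENSMUSG00000065440.1) lies on chromosome 9 at 106178840 to 106178927 in an intron of Wdr82. Mir10a (ENSMUSG00000065519.1) is intergenic on chromosome 11 at 96317165 to 96317274, and Mir375 (ENSMUSG00000065616.3) is intergenic on chromosome 1 at 74900658 to 74900721. Mir139 (ENSMUSG00000065446.1) occupies 101475376 to 101475443 on chromosome 7 in introns of Pde2a, a phosphodiesterase gene, and of the predicted gene Gm45837. Mir22 (ENSMUSG00000065529.1) occupies 75463716 to 75463810 on chromosome 11 in an exon of Mir22hg.

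With at least 10 reads required in each library, 328 of the 2202 annotated miRNA genes were detected. A level of at least 100 CPM in both libraries was reached by 155 genes, 1000 CPM by 65 and 10000 CPM by 19. In the deeper library, replicate 2, 52 genes passed the minimum that replicate 1 did not reach, against 8 genes the other way round. No read was counted on 1460 genes in the both-strand column of either library. Of these, 35 had reads in the strand column and 959 share a 20-base stretch with another miRNA gene, so that their 0 sets no limit on expression. For the 479 genes with neither, a count of 0 allows up to 0.949 CPM of uniquely assigned reads in replicate 1 and 0.490 CPM in replicate 2. The 20-base search covered annotated miRNA genes only. Reads that match elsewhere in the genome may thus still be missing from these genes, so the limit may not hold for expression. With a minimum of 1 read in place of 10, 572 genes were detected.

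Groups of miRNAs fixed in advance described the tissue. The let-7 family, which is low in early embryos and high in differentiated tissue, took 34.1% ± 3.06 of the reads (SD, n = 2), with 10 of 12 members detected (all 12 in the strand column). The miR-10 and miR-196 genes of the Hox clusters took 8.42% ± 0.771, led by Mir10a and by Mir10b at 19108 ± 715 CPM. The neuroendocrine list took 5.65% ± 0.256, most of it from Mir375, with Mir7b at 4526 ± 69.4 CPM and Mir7-1 at 299 ± 9.66 CPM. The list of miRNAs linked to corticotropin (ACTH) response and steroid synthesis took 5.45% ± 0.234, with 14 of 16 members detected (all 16 in the strand column). Its leading members were Mir21a at 23366 ± 11881 CPM, Mir125a at 17313 ± 10607 CPM and Mir34a, a target of the tumor suppressor p53, at 3587 ± 335 CPM. The smooth muscle list took 2.59% ± 0.227, from Mir143 and from Mir145a at 1177 ± 291 CPM. The miR-30 family took 1.36% ± 0.036, or 1.76% ± 0.340 in the strand column described below, which adds Mir30e, and the miR-29 family 1.58% ± 0.432, with Mir29a at 14236 ± 4353 CPM. Sequence shared with another miRNA gene may undercount 6 of 12 let-7 genes, 5 of 16 of the ACTH list and 3 of 4 of the miR-29 family. The same holds for 2 of 6 genes each of the miR-30 and Hox cluster lists and 2 of 4 of the neuroendocrine list.

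Reads counted on markers of other tissues were few, though some members share sequence with another miRNA gene and are undercounted. These are 14 of 16 genes of the neuronal list, 5 of 9 of the striated muscle list, 2 of 4 each of the kidney and intestine and the brown fat lists, and 2 of 7 of the immune list. Mir122, the dominant miRNA of liver, was at 106 ± 23.2 CPM, which is 0.00899% of reads in replicate 1 (exact Clopper-Pearson 95% interval 0.00797 to 0.0101%) and 0.0123% in replicate 2 (0.0114 to 0.0132%). The kidney and intestine list took 0.00524% ± 0.00194, with Mir192 at 26.3 ± 10.3 CPM. The striated muscle list took 0.000786% ± 0.000141, with Mir499 as its only detected member at 4.12 ± 1.34 CPM. No gene of the pancreas list reached 10 reads in both libraries. The epithelial list took 0.106% ± 0.00479, led by Mir203 at 1008 ± 59.5 CPM, whereas Mir200c was at 30.6 ± 4.19 CPM. The brown fat list took 0.174% ± 0.0125, led by Mir455 at 1228 ± 392.2 CPM, which also stands in the ACTH list. The immune list took 0.240% ± 0.00328, with Mir146 at 1447 ± 202 CPM, a gene that shares sequence with another miRNA gene, Mir150 at 570 ± 118 CPM and Mir155 at 289 ± 35.7 CPM. The neuronal list took 0.0973% ± 0.0316, led by Mir137 at 634 ± 145 CPM, and 0.179% ± 0.122 in the strand column described next, led there by Mir129-2 at 917 ± 955 CPM, a gene that shares sequence with another miRNA gene.

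Endothelial and red cell markers depended on which count column was read. In part so did other lists, among them the neuronal, immune, ACTH, Dlk1-Dio3, let-7 and miR-30 ones. Some genes of these lists overlap an annotated miRNA gene on the opposite DNA strand. In the both-strand column, used for the values above, Mir126a, the miRNA of blood vessel endothelium hosted by Egfl7, had 2 reads in replicate 1 and 10 in replicate 2. In the column that counts 1 strand, it had 206095 and 287602 reads, or 49108 ± 10714 CPM (SD, n = 2), rank 4 of all genes. That is 5.67% of the strand-column reads in replicate 1 (exact Clopper-Pearson 95% interval 5.64 to 5.69%) and 4.15% in replicate 2 (4.14 to 4.17%). Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 at 26591357 to 26591429, in an exon of Egfl7, and its opposite-strand partner is Mir126b. Mir451a, the main miRNA of red blood cells, had no read in the both-strand column and stood at 265 ± 162 CPM in the strand column, with its neighbor Mir144 at 36.2 ± 16.5 CPM there. The red cell list took 0.00414% ± 0.00193 in the both-strand column and 0.0319% ± 0.0180 in the strand column.

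In all, 29 genes had at least 10 strand-column reads in each library and under 10% of these in the both-strand column, and 24 of them had no both-strand read. This definition was chosen after the values were seen. Among them were Mir378a, from an intron of the metabolic coactivator gene Ppargc1b, at 38774 ± 4673 CPM in the strand column, a count that is uncertain because of shared sequence, Mirlet7e at 14993 ± 1899 CPM, Mir191 at 8255 ± 376 CPM and Mir30e at 5686 ± 3854 CPM. Together the 29 genes held 13.1% of strand-column reads in replicate 1 and 11.6% in replicate 2. All 29 overlapped an opposite-strand miRNA gene, against 0 of the other 327 genes detected in the both-strand column. Moving to the strand column lowered Mirlet7b to 107083 CPM and the share of the leading 10 genes to 55.0%.

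**Figure D2:**
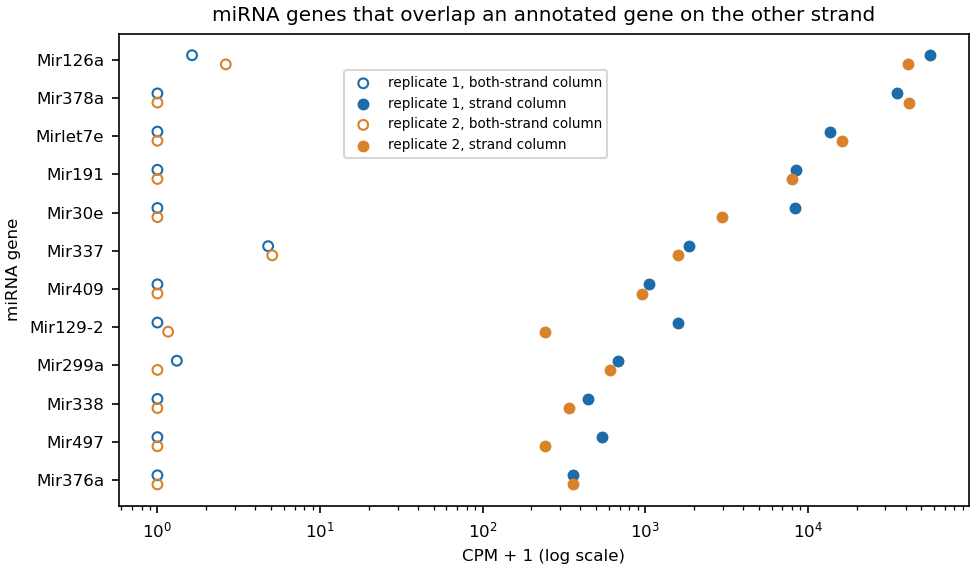
CPM + 1 on a log axis for the 12 most abundant of the 29 genes counted almost only in the strand column, with open symbols for the both-strand column and filled symbols for the strand column of each library. Mir126a stands at 1.13 CPM on average in the both-strand column and at 49108 CPM in the strand column, and Mir378a at 0 and 38774 CPM.

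The imprinted Dlk1-Dio3 region, a large cluster of miRNA genes expressed from the maternal chromosome, took 6.71% ± 0.386 of reads (SD, n = 2), with 40 of 54 listed genes detected (46 in the strand column). Mir127 led at 22539 ± 6897 CPM, followed by Mir411, which shares sequence with another gene, at 9091 ± 467 CPM and Mir379 at 7744 ± 3500 CPM. Mir127 (ENSMUSG00000070076.2) lies on chromosome 12 at 109592846 to 109592915, opposite to an exon of Rtl1. Across the genome, neighboring miRNA genes on the same strand within 10 kb had closer levels than randomly paired genes. Over 95 pairs among the 328 detected genes, the mean absolute difference in log2 CPM was 2.91, against 4.10 when levels were permuted among genes (permutation test, one-sided, p = 2e-05). Of these pairs, 36 lay within the Dlk1-Dio3 list, and the 59 others gave 3.09 against 4.10 (permutation test, p = 0.00339), a split chosen after the data were seen. Levels within a pair could still differ widely, as for Mirlet7b and Mirlet7c-2 at 122191 and 1173 CPM, a pair picked after its values were seen, of which the second shares sequence with another gene. The test treats genes as the unit and says nothing about differences between animals.

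The next question was how closely the 2 libraries matched. Mir26a-2, in an exon of Ctdsp2, was higher in replicate 2, at 395 CPM against 34.2 CPM in replicate 1, a log2 ratio of 3.52 with an adjusted p of 3.31e-294 by Fisher's exact test (two-sided, Benjamini-Hochberg). It shares sequence with Mir26a-1, so its count is uncertain. Mir674 was higher in replicate 2 at 6377 against 1483 CPM, with a log2 ratio of 2.10, followed by Mir298 with 1.88, Mir31 with 1.70 and Mir1839 with 1.63. Mir185, in an intron of Tango2, was lower in replicate 2 at 118 against 1094 CPM, a log2 ratio of -3.21. Mir129-1, a miRNA of neurons that also shares sequence with another gene, was lower with a log2 ratio of -2.47. Mir125a, Mir222 and Mir434 were lower with log2 ratios of -1.34, -1.22 and -1.16. Among the most abundant genes, Mir21a had a log2 ratio of 1.09 and Mir379 of 0.96.

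Of 426 genes tested by Fisher's exact test, 217 differed between the libraries, 66 higher and 151 lower in replicate 2. The balance depended on scaling, as with TMM normalization 215 genes were called, 106 higher and 109 lower, and with DESeq2 size factors 216, 109 higher and 107 lower. TMM shifted every log2 ratio by 0.18, moving the median over detected genes from -0.20 to -0.02, and relative to it Mir26a-2 stood at 3.70 and Mir185 at -3.04. Fisher's test allows for counting error only and compares these libraries, not conditions. When the spread between the libraries was included, through edgeR's exact test with a common dispersion, 4 genes were called after Benjamini-Hochberg adjustment. They were Mir26a-2 (adjusted p = 0.000308), Mir185 (adjusted p = 0.000765), Mir129-1 and Mir153 (both with adjusted p = 0.0352). Of the 426 genes, 22 were at an unadjusted p under 0.05 by edgeR's exact test, close to the number such a threshold passes when no gene differs. Mir153, another neuronal miRNA, was named here after its values were seen and had a log2 ratio of -2.50. The other named genes were not called by it, with adjusted p of 0.105 for Mir674, 0.185 for Mir298, 0.328 for Mir31, 0.410 for Mir1839 and 0.819 for Mir125a, and of 1 for Mir222, Mir434, Mir21a and Mir379. That test takes its dispersion from the same libraries, and no replicate check of it exists.

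**Figure D3:**
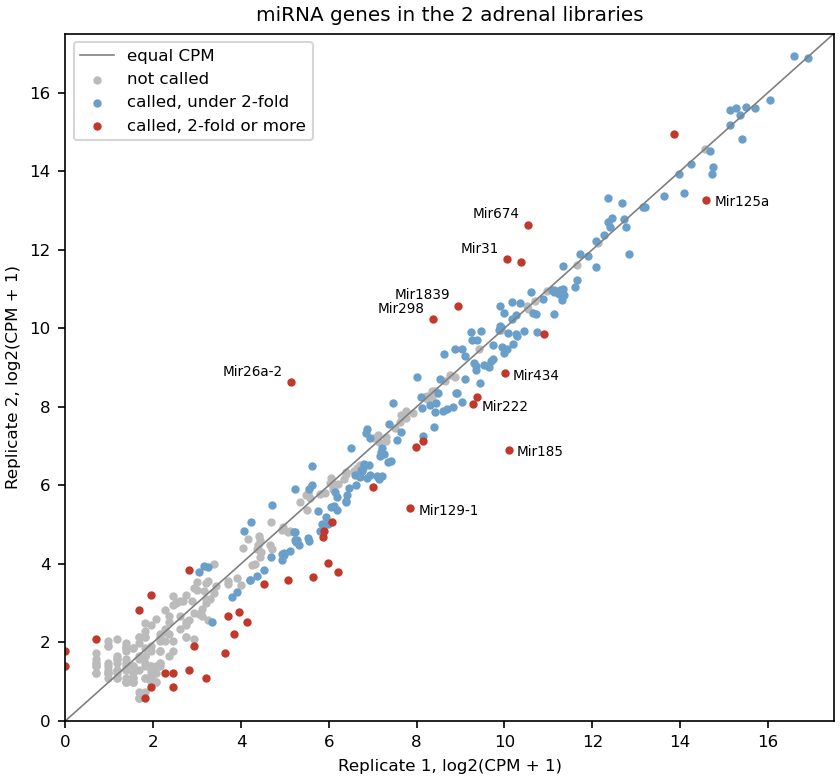
Level of each of the 426 tested miRNA genes as log2(CPM + 1) in replicate 1 and replicate 2, with the line of equal CPM and the genes called by Fisher's exact test in color. Mir26a-2 lies well above the line with a log2 ratio of 3.52, and Mir185 well below it with a log2 ratio of -3.21.

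The profile as a whole was shared. Across the 426 genes, which are not independent replicates, log2(CPM + 1) correlated with Pearson's r = 0.985 and Spearman's rho = 0.971, and 22 of the 25 most abundant genes of each library were common to both. Of the 328 detected genes, 64.6% lay within 1.5-fold and 89.6% within 2-fold of equal CPM. Among all 426 tested genes, which include genes with under 10 reads in a library, 44 called genes differed at least 2-fold, 13 higher and 31 lower in replicate 2. The counts differed far beyond sampling noise, with a chi-square of 194343 on 425 degrees of freedom, so the tables are not 1 library deposited again, which leaves open whether the samples came from separate animals. The between-library biological coefficient of variation was 30.8% over 328 genes (edgeR common dispersion), and the median over genes from DESeq2 was 15.4%. The median absolute log2 ratio was 0.51, 0.42, 0.38 and 0.27 for genes with a mean of at least 10, 100, 1000 and 10000 reads and below the next of these limits, whereas the SD of the log2 ratio did not fall steadily with depth, at 0.67, 0.61, 0.73 and 0.64.

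Groups differed between the libraries in both directions. Counts of calls adjusted over the list alone equalled those over all genes in the both-strand column, except for 1 more gene each in the neuroendocrine and Dlk1-Dio3 lists. In the let-7 family 7 detected members were higher in replicate 2, 2 were lower and 1 was not called by Fisher's exact test. Mirlet7g had a log2 ratio of 0.35 and Mirlet7d of 0.34. The list's median log2 ratio was 0.14 with plain totals, at percentile 97.0 of random lists matched on abundance, and with TMM normalization the median was 0.32, with 9 members higher and 0 lower. Of the 21 lists placed in this way, let-7 and the miR-26 family, at percentile 99.3, stood above 90, and the miR-99 and miR-100, embryonic stem cell and brown fat lists, at 0.19, 5.93 and 8.95, stood below 10. In the strand column the ACTH list, at 91.1, also stood above 90 and the red cell list, at 2.99, below 10, whereas the brown fat list stood at 12.4. Among 21 lists several would fall beyond these limits by chance alone, and no correction for their number was made. The random lists also take no account of list members that lie in the same genomic cluster and are not independent. The miR-26 median is that of Mir26a-1, which had 14 and 49 both-strand reads, a log2 ratio of 0.82 and no call. Mir26b, which holds nearly all reads of that family, stood at -0.01. All 3 genes of the miR-99 and miR-100 list were lower in replicate 2 with plain totals, TMM and DESeq2 size factors (median log2 ratio of -0.80 with plain totals). These were Mir99a at 27242 and 15635 CPM, Mir99b at 7351 and 3768 CPM, and Mir100 at 3102 and 2135 CPM in replicates 1 and 2. The 11 detected genes of the miR-17-92 and related clusters, which promote proliferation, held 8 lower and 3 not called, and 7 lower with TMM. Mir17 among them was at 1480 ± 189 CPM. The ACTH and steroid synthesis list held 7 higher, 4 lower and 3 not called (8 higher and 3 lower with TMM). Mir132, which is induced through cAMP signaling, was at 1391 ± 331 CPM with a log2 ratio of 0.49, and was named outside the rule after its values were seen. The Dlk1-Dio3 list held 9 higher, 21 lower and 10 not called (9 and 22 adjusted over the list alone), and 13 higher and 17 lower with TMM. The neuronal list held 1 higher, 4 lower and 1 not called (3 lower with TMM), and 2 of its members, Mir129-1 and Mir153, were lower by edgeR's exact test. The Hox cluster list held 4 lower and 2 not called (1 higher and 2 lower with TMM), and the neuroendocrine list 2 lower and 2 not called (1 higher and 2 lower adjusted over the list alone, 3 higher and 1 lower with TMM). Both smooth muscle genes were lower, whereas with TMM Mir143 was higher and Mir145a lower. The immune list held 1 higher and 3 lower (1 and 1 with TMM), the epithelial list 1 and 1 with 3 not called, the brown fat list 1 and 2 with 1 not called, and the miR-30 family 2 and 2 with 1 not called (3 and 1 with TMM). In the strand column the miR-30 family held 2 higher, 3 lower and 1 not called, and its share was 2.00% in replicate 1 and 1.52% in replicate 2, against 1.34% and 1.39% in the both-strand column. In the miR-29 family 2 genes were lower and 2 not called (1 higher and 1 lower with TMM). Both kidney and intestine genes were lower, and Mir122 was higher (Fisher's exact test, adjusted p = 1.68e-05). With edgeR's exact test no member of the let-7, miR-99 and miR-100, miR-17-92, ACTH or Dlk1-Dio3 lists was called.

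Differences between the libraries were not detectably shared by neighboring genes. The correlation of the log2 ratios of neighbors was 0.0149 over 95 pairs (permutation test, one-sided, p = 0.428). In the cluster within Spaca6 on chromosome 17, Mir99b and Mir125a were lower in replicate 2 with strand-column log2 ratios of -0.94 and -1.31, and Mirlet7e between them was higher with 0.26, a cluster singled out after its values were seen.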

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

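The test of low counts in duplicated families, and the definition of the genes seen almost only in the strand column, were chosen only after the result was seen.

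A first pattern came from a column outside the main measurement. There, 29 genes had at least 10 strand-column reads in each library and under 10% of them in the both-strand column, among them Mir126a, Mir378a, Mirlet7e and Mir191. The values show that the authors' counting left out reads over overlapping annotated genes there. Of these genes 100% overlap an opposite-strand miRNA gene and 0 of the other 327 detected genes do. Mir337, which overlaps and is still detected, is among the 29. The 29 genes held 13.1% of strand-column reads in replicate 1 and 11.6% in replicate 2, and the ambiguous reads came to the same 13.1% and 11.6%. These matches largely follow from how the columns add up and are no separate test. The both-strand zeros thus do not speak of expression. No biological explanation was tested, as the design has 1 group.

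These reads are listed because they lie outside the main measurement. Multimapping reads, which were assigned to no gene, made up 31.6% of reads in replicate 1 and 33.6% in replicate 2, and the low counts of duplicated miRNA genes form another pattern. Mir26a-1 stood at 6.22 CPM, against 24154 CPM for its relative Mir26b. Within 8 families, members that share a 20-base stretch with another miRNA gene lay below their relatives in strand-column CPM, with a mean log2 difference of -4.72 (permutation test, p = 1e-04). This suggests that reads shared between paralogs were lost, although the miR-15 and miR-16 family differed by 0.49 in the other direction. True differences in expression between family members stay open as well and were not tested.

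Reads in the column of the other strand, beyond the ambiguous ones, numbered 235 in replicate 1 and 337 in replicate 2 over all genes. At Mir203 there were 172 reads of the other strand in replicate 1 and 213 in replicate 2, above the limit of 3 that a count of 0 allows for 1 gene.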

How the results depend on the processing

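The use of edgeR's exact test on the strand column and the restriction of neighbors to pairs outside the Dlk1-Dio3 list were chosen only after the result was seen. No paired analysis was possible because the labels give 1 group. Among values of single genes and lists, 608 moved by less than the SD between replicates or kept their call, 93 moved further, and 7 log2 ratios lost their call, each under edgeR's exact test. These counts leave out the settings without a replicate, since with 2 replicates the mean then moves by less than the SD whatever the values. Of the 87 single genes, 15 moved over 1.5-fold without 1 of the replicates, such as Mir26a-2 (34.2 to 395 CPM) and Mir185 (118 to 1094 CPM). Of the same 87, 28 moved beyond the SD in the strand column and 32 with totals without Mirlet7b. Both settings rescale nearly all of these genes alike, so the 28 and 32 do not tell which genes depend on the setting. With at least 1 read, 572 genes were detected in place of 328, and leaving out a replicate gave 336 to 380. Mirlet7b moved from 122191 CPM to 107083 in the strand column and to 139200 with itself left out of the totals. That total also lowered the let-7 share from 34.1% to 24.96%, Mirlet7b then being left out of the family, and the share of the leading 10 genes was 55.0% in the strand column, which adds the reads of 29 genes. Leaving out a replicate gave shares of 58.5% to 61.7% for the leading 10 genes, 32.0% to 36.3% for let-7 and 121853 to 122529 CPM for Mirlet7b. The leading 10 were picked anew in the library kept, so replicate 2 alone has Mir21a in place of Mir23a. The coefficient of variation fell from 30.8% to 15.4% with DESeq2's gene-wise median, a median rather than 1 value fitted to all genes, and lay between 30.3% and 32.3% otherwise. Fisher's exact test called 217 of 426 genes in the both-strand column and 239 of 455 in the strand column, and edgeR's exact test, which adds the spread between libraries, 4 and 5. Of these, 4 genes were common to both columns, and the other, Mir129-2, was not tested in the both-strand column. Spearman's rho fell from 0.971 to 0.916 with genes of at least 1 read, which adds genes near the floor. Neighbors had closer levels under every setting, with ratios to the permuted mean of 0.661 to 0.834. The correlation of their library differences changed sign in the strand column (-0.0393), within 50 kb (-0.00442) and outside Dlk1-Dio3 (-0.0390), where the cause was not tested, and no setting passed the permutation test. TMM and DESeq2 scaling cannot move that correlation, as values are centred, nor can scaling or a pseudocount move Spearman's rho. Depth limits the genes near 10 reads, where 52 were detected in the deeper library alone.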

Other observations

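The comparison without the Mir26a pair and edgeR's exact test on the strand column were chosen only after the result was seen.

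Other groups fixed in advance filled in the profile. The miR-99 and miR-100 list took 2.96% ± 1.14 of reads (SD, n = 2) and the miR-26 family 2.44% ± 0.0147, nearly all from Mir26b, with 1 member higher in replicate 2 and 2 not called by Fisher's exact test (3 higher with TMM). Of the 3 miR-26 genes, 2 share sequence with another miRNA gene and are undercounted, so the lead of Mir26b may come from the counting. The miR-15 and miR-16 family took 1.48% ± 0.190, led by Mir322 at 11606 ± 1573 CPM, with 3 members higher, 2 lower and 1 not called. The miR-17-92 and related clusters took 0.653% ± 0.127 and the miR-181 family 0.171% ± 0.0252, with 3 lower and 3 not called (1 higher and 1 lower with TMM). The gonad list took 0.235% ± 0.0444, mostly Mir34c at 2146 ± 373 CPM, with all 4 detected members lower in replicate 2 by Fisher's exact test and 3 with TMM. The miR-183 cluster, known from sensory organs, took 0.151% ± 0.0233, with Mir182 at 891 ± 253 CPM and Mir96 at 38.5 ± 32.9 CPM, 1 member being higher and 2 lower. The embryonic stem cell list took 0.0345% ± 0.0113, led by Mir302a at 105 ± 42.7 CPM, a gene that shares sequence with another, and 5 of its 6 detected members were lower in replicate 2 by Fisher's exact test, 5 with TMM and 4 with DESeq2 size factors. These 6 are not independent, as Mir302b, Mir302c, Mir302a and Mir302d are consecutive genes of 1 cluster, and Mir293 and Mir294 are neighbors. The Sfmbt2 cluster took 0.0648% ± 0.0145, with 3 lower and 1 not called (2 lower with TMM). It is undercounted, as 28 of its 29 genes share sequence with another miRNA gene, which also holds for 4 of 6 genes of the miR-181 family, 4 of 14 of the embryonic stem cell list and 6 of 21 of the X-linked cluster. The miR-148 and miR-152 list took 0.0603% ± 0.00927, with 1 lower and 2 not called (1 higher and 1 lower with TMM). Hypoxia-induced Mir210 took 0.0147% ± 0.00111 and was not called, though higher with TMM, and the X-linked cluster took 0.00128% ± 0.000607, with Mir547, at 10.2 ± 6.13 CPM, as its only detected member, which was lower. The pancreas list took 0.000113% ± 2.53e-05, and the endothelial list 4.91% ± 1.07 of the strand-column reads.

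Several markers of neurons and red cells, singled out after their values were seen, were lower in replicate 2. In the strand column Mir129-2 was at 1593 CPM in replicate 1 and 242 CPM in replicate 2, and its paralog Mir129-1 and Mir153 were lower too. The neuronal list, however, also held Mir128-1, with a both-strand log2 ratio of 0.70. In the strand column the list had 1 member higher, 5 lower and 3 not called by Fisher's exact test (2 higher and 5 lower adjusted over the list alone), and its median stood at percentile 19.5 of matched lists, against 34.4 in the both-strand column. Of the red cell markers, Mir451a had a strand-column log2 ratio of -1.34 and Mir144 of -0.96, while Mir486 at -0.24 was not called by Fisher's exact test. On the strand column edgeR's exact test called Mir129-2 and none of these red cell markers, but it sets 1 library against 1 with a dispersion from the same libraries, so these differences have no replicate check.

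The differences between the libraries were set against technical causes. The values argue against GC content of the precursor, as Pearson's r with the log2 ratio was -0.00194 across 328 genes (SE 0.0553). The sequenced molecules are only a part of the precursor, and their own GC content was not tested. Sequence-dependent ligation or amplification may contribute. Genes at separate loci that share a 12-base stretch of the precursor had log2 ratios correlated at 0.204 over 108 pairs (permutation test, p = 0.0178). The correlation fell to 0.127 (permutation test, p = 0.0821) without the pair of Mir26a genes. A stretch of that length also pairs genes of separate families, such as Mir30a and Snord43, so it is a loose measure of similarity. Shared primary transcripts gave a correlation of 0.0149 among neighbors, with a permuted SD of 0.102. That spread keeps the transcripts open, and ligation cannot be told apart from shared counts of similar genes; differences between animals, for which the design gives no contrast, were not tested.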
